A study of Homo sapiens with 4 samples.

How the data were processed

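NB4 cells, an established human acute promyelocytic leukaemia line that matures along the granulocyte lineage when given all-trans retinoic acid (ATRA), were cultured for 72 h with vehicle (DMSO), 100 nM ATRA, 10 µM 6AF or both reagents, per the labels. 6AF is known here only as a fucosylation inhibitor, from the series title. Total RNA of each of the 4 cultures was labelled with biotin and hybridised by an Affymetrix protocol, 1 array per treatment.

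The deposited table holds log2 signals of 21448 transcript clusters on the 4 arrays. The log2 scale was read from the values, which run from 2.1 to 18.58 with 2 decimals. Per the submitters' processing notes the arrays were processed with Transcriptome Analysis Console. The version, the summarisation and the normalization between arrays are not given in the sources used here. A fold printed here is therefore a fold in processed signal, and may be larger or smaller than the fold in RNA. The sorted values of the 4 arrays differed by at most 0.41 at any rank, and array medians lay between 6.185 and 6.27, so no further scaling was applied in the results given first. Detection calls and probe-level signals were not used here, so a dim signal could not be told from background, and a log2 difference against a dim array can understate the change by an unknown amount.

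Gene symbols came from the platform annotation, and all symbols matched RefSeq by Entrez identifier. Of the clusters, 17709 had 1 gene symbol, 0 had several, and 3739 were unnamed here and entered no comparison of genes. For the 20 genes with more than 1 cluster, the cluster with the highest mean signal was kept, which left 17687 genes. No genomic coordinates are printed because the sources used here name no genome build. Near-identical genes (DEFA1 and DEFA3, the HBA and IFITM families, and NCF1 with its pseudogenes) can share probe sequence, so their values are uncertain individually.

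With 1 array per treatment, no difference has a replicate check. No p-value, standard error or interval was computed, and the number of arrays limits the precision of every value. Each of the 5 pair differences was a subtraction of log2 signals. A gene was counted when its difference was at least 1 in size (2-fold) and the higher of the compared arrays reached an expression floor of 6.42, the median of all gene values. The difference of differences was (ATRA+6AF minus 6AF) minus (ATRA minus DMSO). The 2 ATRA differences share no array, nor do the 2 6AF differences (6AF minus DMSO and ATRA+6AF minus ATRA), so agreement within each of those pairs does not come from a shared control. The ATRA response set was chosen on the mean of the 2 ATRA differences, which treats the arrays with and without 6AF alike.

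Before the data were examined, 26 gene lists were fixed. Together they held 695 entries, of which 621 were measured. Each list's median difference was placed among the medians of 10000 random lists of the same size matched on mean signal in 20 bins. A list is said to stand apart when its median lay at or below the 2.5th or at or above the 97.5th percentile. This describes these arrays and is not a p-value. Of random lists of unrelated genes, 1 in 20 lies that far out in any comparison. Genes of a fixed list can vary together between cultures, so how often such lists stand apart by chance was not measured. Named genes were also set by rule. For each reagent they were the 10 highest and 10 lowest genes by the smaller of its 2 same-signed differences. For ATRA+6AF minus ATRA they were the 10 highest and 10 lowest, and for ATRA+6AF minus DMSO and the difference of differences the 5 highest and 5 lowest. Up to 4 members with the largest differences, and any member past the 2-fold rule, could be named from each list, together with 8 genes fixed by name.

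The alternatives were a threshold of 1.5-fold or 3-fold, no floor or a floor at the 75th percentile, centring each array on its median, quantile normalization, cyclic loess, the mean of a gene's clusters, unmatched random lists, and list means in place of medians. Random lists matched on the mean ATRA difference or on gene length (the genomic span in RefSeq) were added after seeing the data, the latter also for gene families. Analyses used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, with R 4.3.3 and limma 3.58.1 for quantile and cyclic loess normalization.

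The counting rule was tested on simulated arrays of 17687 genes with noise set from the 6AF minus DMSO differences. That noise was drawn as normal, and its size holds any effect of 6AF. Differences were planted only in genes at or above the floor on the simulated DMSO array, so the rates do not cover genes that start dim. For a simulated ATRA minus DMSO comparison, 100% of 50 genes planted at 4-fold were counted and 46% of 50 genes planted at 2-fold, with 23 unchanged genes counted. Requiring both ATRA differences left 0 unchanged genes but counted 20% of the genes planted at 2-fold and 0% of those planted at 1.5-fold, so that rule misses most small differences. In a simulated 6AF minus DMSO comparison, 2 of 40 unchanged lists stood apart. Those lists held randomly drawn genes with independent noise, so the rate for genes that vary together was not covered.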

Results

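The series asked how a fucosylation inhibitor, 6AF, affects the differentiation of NB4 promyelocytic leukaemia cells by ATRA, the retinoid that drives these cells towards granulocytes. Gene expression was measured on 4 arrays, 1 each for DMSO, ATRA, 6AF and ATRA+6AF at 72 h. No treatment was replicated, so each value below is a single log2 signal or a difference of log2 signals, and whether a difference exceeds the spread between cultures was not measured. The arrays fell into pairs by ATRA. Across all transcript clusters the correlation was 0.993 between DMSO and 6AF and 0.991 between ATRA and ATRA+6AF, against 0.958 to 0.963 for the pairs that differed in ATRA.

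ATRA given alone was accompanied by large expression differences in genes of granulocyte maturation, retinoid response, chemokine and interferon biology. Relative to DMSO, 781 genes were at least 2-fold higher and 1230 at least 2-fold lower among 9395 genes above the floor. In the presence of 6AF the corresponding numbers were 994 and 1154 of 9353. Of these, 651 genes were higher and 735 lower in both ATRA comparisons, where independent lists would share 77.6 and 148.2. Only HCP5, a dim transcript, passed 2-fold in opposite directions. The 2 ATRA differences had a Pearson correlation of 0.912 across genes above the floor (genes are not independent replicates). The balance of higher and lower genes depended on scaling. Cyclic loess gave 956 higher and 895 lower genes for ATRA minus DMSO, 1147 and 865 for ATRA+6AF minus 6AF, and 770 and 541 for both.

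The 10 genes with the largest positive ATRA differences in both backgrounds were TGM2, CCL24, CLC, CCL2, ALOX5AP, DEFA4, NCF1, LGALS9, S100A8 and BCL2A1. TGM2, a transglutaminase and known retinoid target, had a log2 signal of 5.61 with DMSO and 17.03 with ATRA, a difference of 11.42, and 11.43 in the presence of 6AF. The chemokines CCL24 and CCL2 differed by 10.08 and 9.64 with ATRA alone. CLC, which encodes the Charcot-Leyden crystal protein of eosinophils and basophils, differed by 9.93, and ALOX5AP, the activating protein of leukotriene synthesis, by 9.52. The neutrophil defensin gene DEFA4 was higher by 9.32, the NADPH oxidase subunit gene NCF1 by 8.63, the calprotectin subunit gene S100A8 by 8.25, and the BCL2 family survival gene BCL2A1 by 8.09. LGALS9, which encodes galectin-9, was higher by 8.50. All but ALOX5AP, NCF1 and DEFA4 started below the floor on the DMSO array.

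The 10 lowest genes by the same rule were CYTL1, CST7, BCL2, EBF3, BCL11A, MMP2, HGF, MOK, MMP9 and LHFPL6. CYTL1, a cytokine-like gene of haematopoietic progenitors, had a log2 signal of 13.47 with DMSO and 3.40 with ATRA, a difference of -10.07, and differed by -9.10 in the presence of 6AF. The leukocyte cystatin gene CST7 differed by -6.79 and the growth factor gene HGF by -6.36. BCL2, the founding anti-apoptotic gene of its family, differed by -5.63, opposite in direction to BCL2A1. The transcription factor genes EBF3 and BCL11A differed by -5.45 and -5.36, and the matrix metalloproteinase genes MMP2 and MMP9 by -5.87 and -4.57. MOK and LHFPL6 differed by -5.11 and -5.64.

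**Figure D1:**
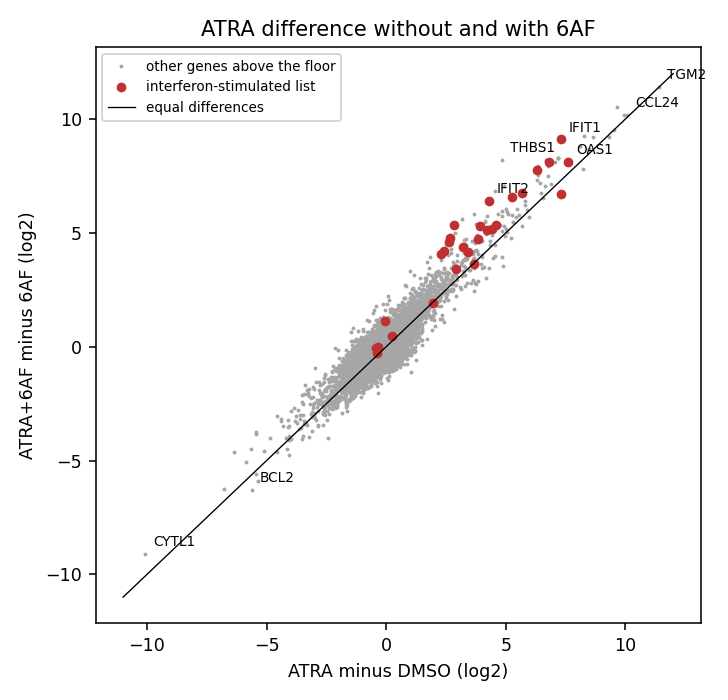
Each point is a gene above the expression floor, with the log2 difference ATRA minus DMSO on the x axis and ATRA+6AF minus 6AF on the y axis, 4 arrays in all; red points are the interferon-stimulated list and the line marks equal differences. Most genes lie along the line (Pearson correlation 0.912), and most interferon-stimulated genes with a large difference lie above it.

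Of the 26 fixed lists, 9 stood apart as higher and 4 as lower in ATRA minus DMSO. Interferon-stimulated genes had the largest list median, 2.88, with 23 of 34 measured members at least 2-fold higher and 0 lower. Retinoic acid response and metabolism genes had a median of 1.94, with 10 of 20 higher and 0 lower. Besides TGM2 these included ASB2 (5.57), TNFAIP2 (5.41) and the ectoenzyme gene CD38 (4.54), while CYP26A1, the retinoic acid hydroxylase, differed by 1.85 from a dim signal of 4.83. Mature neutrophil and phagocyte genes had a median of 1.64, with 18 of 28 higher and 1 lower. Among them the integrin genes ITGB2, ITGAM and ITGAX (CD18, CD11b and CD11c) differed by 3.82, 2.75 and 2.58, the peptidylarginine deiminase gene PADI4 by 6.33 and the adhesion gene CEACAM1 by 7.07, and the single lower member was TREM1 at -1.71. Chemokines and inflammatory mediators had a median of 1.30, with 13 of 28 higher and 0 lower, among them CXCL10 (5.89), ICAM1 (5.29) and IL1B (4.68).

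Granule genes did not all differ in the same direction. Of the 20 secondary and tertiary granule genes, 4 were at least 2-fold higher and 1 lower, with a median of 0.43. The higher members were S100A8 and S100A9 (6.68), which encode the calprotectin subunits, ARG1 (2.48) and CTSS (1.77), and MMP9 was the lower one. S100A12 differed by 2.54 with signals under the floor on both arrays. LTF, CAMP and LCN2, the classical secondary granule genes, had signals under the floor with and without ATRA. Primary granule genes had a median of -0.30, inside the range of random lists matched on signal, but a mean of 1.28, with 6 of 18 higher and 4 lower. Among random lists matched on gene length the list stood apart as lower. The higher members included DEFA4, DEFA1 (7.19), BPI (6.42) and PRTN3 (1.56), and the lower members were PRSS57 (-3.50), CTSG (-1.52), MS4A3 (-1.39) and SERPINB10 (-1.37). Under quantile normalization the secondary and tertiary granule list no longer stood apart.

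Among myeloid transcription factors (median 0.34) 7 of 25 were higher and 6 lower. Higher were ID2 (5.00), IRF1 (3.99), BCL6 (3.33), CEBPE (2.76), CEBPB (2.34), SPI1 (1.79) and VDR (1.21); CEBPE is required for late granulocyte maturation. Lower were GATA2 (-2.68), IRF8 (-2.42), GFI1 (-2.41), CEBPA (-1.77), MYC (-1.72) and MYB (-1.08). The immature progenitor list had a median of -0.27, with 0 of 20 higher and 6 lower, including HGF, IGFBP2 (-3.49), CDK6 (-1.32) and SOX4 (-1.28), but it did not stand apart with unmatched random lists or with lists matched on gene length. Ribosome biogenesis genes had a median of -0.84 and were lower by any amount in 25 of 25 members, 8 of them by 2-fold or more, such as POLR1B (-2.24), MRTO4 (-1.64) and WDR12 (-1.53). Cell cycle genes had a median of -0.46, with 11 of 49 lower by 2-fold and 0 higher. Those past 2-fold included MCM10 (-1.78), E2F1 (-1.67), CDC25A (-1.30) and UHRF1 (-1.27), whereas MKI67 differed by 0.07 and TOP2A by -0.43. ATF4-linked stress and amino acid genes had a median of -0.45, with SLC7A5 (-3.58) and PHGDH (-2.84) among 4 lower members and SLC7A11 (1.85) among 3 higher.

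Lysosome and autophagy genes had a median of 0.81, with 11 of 24 higher and 2 lower, among them CTSD (5.25), CTSZ (3.17) and SQSTM1 (2.63). The BCL2 family and death receptor list (median 0.55) also stood apart, with 3 of 21 members higher (BCL2A1, CASP8 at 1.65 and MCL1 at 1.02) and BCL2 lower. Monocyte and macrophage markers (median 0.60) had 5 of 25 members higher, including CX3CR1 (3.99), CD68 (2.73) and CD4 (2.35), while CCR2 (-1.69) was lower and CD14 was under the floor on both arrays. The remaining lists lay within the range of random lists matched on signal, although the nucleotide sugar list stood apart as lower with unmatched or length-matched lists, and the glycolysis list with lists matched on the mean ATRA difference. Their medians were 0.34 for erythroid and megakaryocyte markers, -0.05 for lymphocyte markers, 0.19 for eosinophil, basophil and mast cell markers, -0.02 for NOTCH genes, -0.01 for endoplasmic reticulum chaperones, -0.05 for p53 targets, 0.00 for cholesterol genes, -0.06 for glycolysis and hypoxia genes, -0.36 for nucleotide sugar genes and -0.06 for reference genes. The NOTCH, chaperone, p53 and glycolysis medians turned positive under at least 1 other scaling. In the eosinophil list CLC and PRG3 (3.63) were higher while HDC (-4.06) and GATA2 were lower. Its median turned to -0.90 over the 5 members with an array at or above the 75th percentile of signals.

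The genes of the pathway that 6AF targets differed with ATRA in a few members. Over 18 measured genes of GDP-fucose synthesis, transport, transfer and removal the median was 0.09. FUT4, the fucosyltransferase that makes the Lewis X (CD15) antigen of myeloid cells, was higher by 1.33 (9.97 to 11.30), and FUT8, the core fucosyltransferase, was lower by 1.33 on the log2 scale (-1.33). GMDS and GFUS, the enzymes of de novo GDP-fucose synthesis, differed by 0.33 and -0.56, and FUT7 (-0.42) was under the floor. Among selectin ligand genes (median 0.07) SELPLG, which encodes PSGL-1, was higher by 3.65, B4GALT5 by 1.29 and CD24 by 1.02, and CHST4 (-2.08), ST3GAL4 (-1.41) and GCNT2 (-1.19) were lower.

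**Figure D2:**
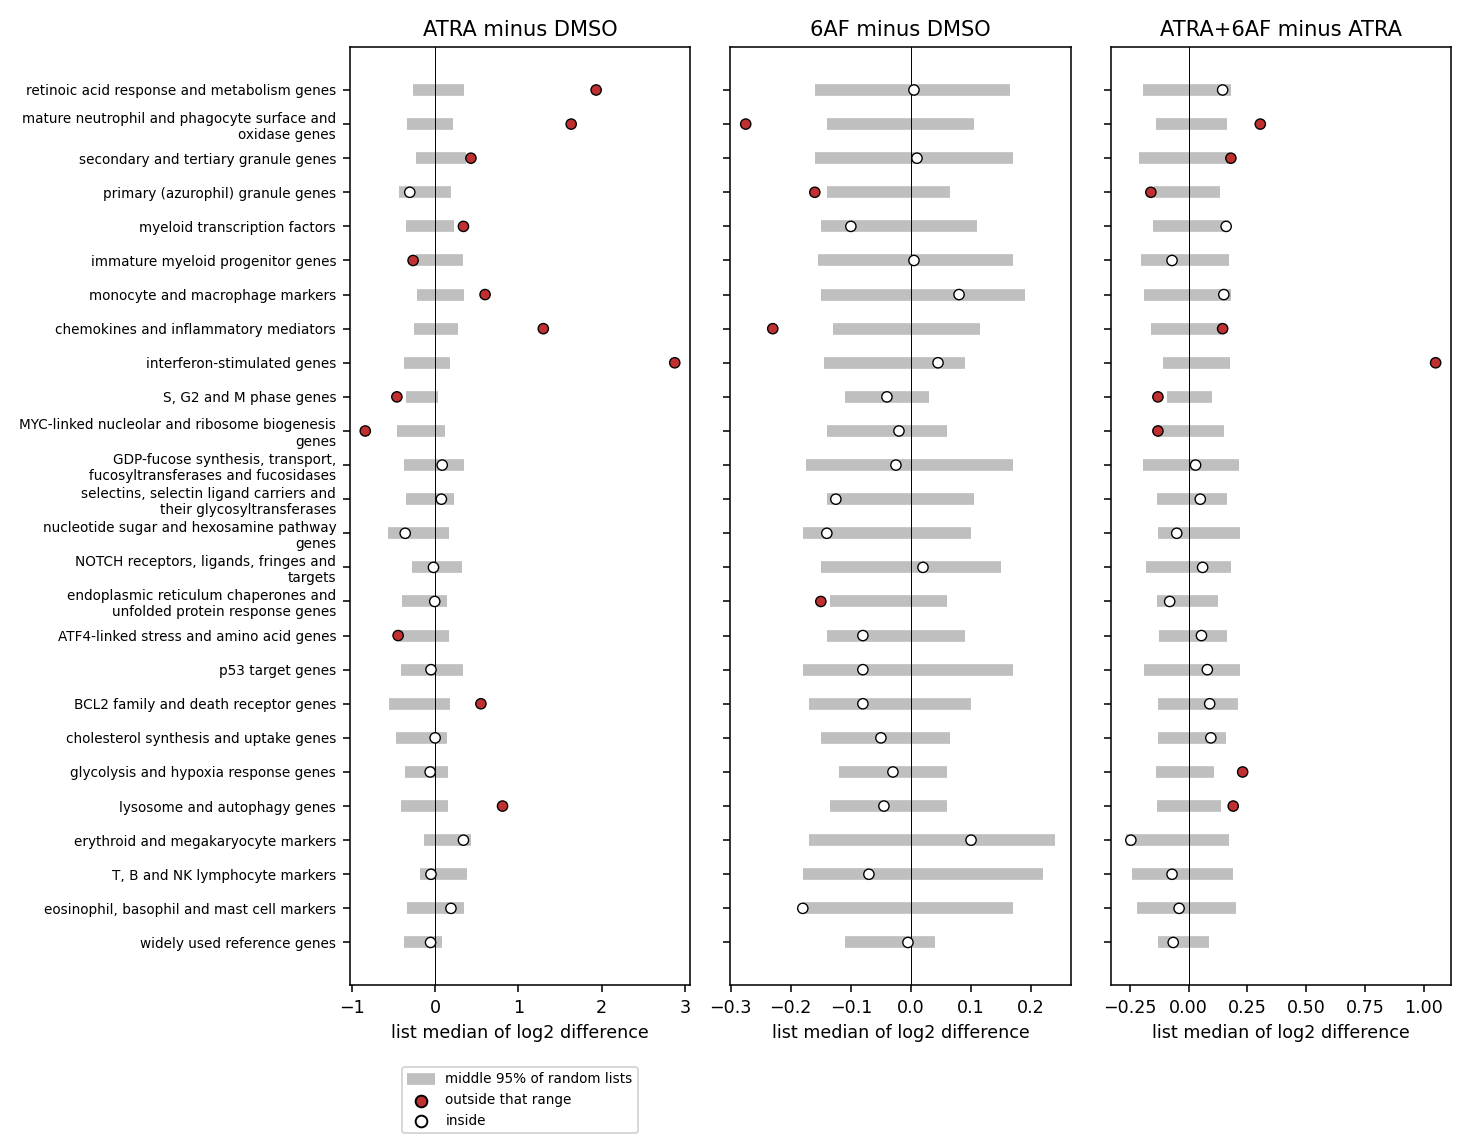
Each dot is the median log2 difference of a fixed gene list in ATRA minus DMSO, 6AF minus DMSO or ATRA+6AF minus ATRA (1 array per treatment, x axes differ in scale); grey bars span the middle 95% of 10000 random lists matched on signal, and red dots lie outside. The interferon-stimulated list has the largest median with ATRA (2.88) and in ATRA+6AF minus ATRA (1.05).

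6AF given alone was accompanied by small differences. Relative to DMSO, 21 genes were at least 2-fold higher and 33 lower among 9064 above the floor, and the split was 13 and 43 with each array centred on its median. With no expression floor it was close to even, 121 and 112. Comparing ATRA+6AF with ATRA, 142 genes were higher and 38 lower, or 230 and 174 with no expression floor. A single gene, SPINT1, a membrane protease inhibitor gene, passed 2-fold the same way in both 6AF comparisons (1.04 and 1.28), where independent lists would share 0.16 higher and 0.05 lower genes. SPINT1 was dim, with log2 signals of 6.1, 6.59, 7.14 and 7.87 with DMSO, ATRA, 6AF and ATRA+6AF, the first under the floor. Under quantile normalization SPINT1 differed by 0.96 with 6AF alone and 0 genes were shared, as with a floor at the 75th percentile. The 2 differences had a Pearson correlation of -0.102 across genes above the floor. Behind SPINT1, the genes highest in both were E2F7 (0.98 and 0.79), AK4 (0.77 and 1.17), NALF2, ASAP3, PARP14 (0.72 and 1.11), MIF4GD, TMEM120A, IFI6 (1.21 and 0.62) and SBF2 (0.62 and 1.03), the last tied with TMEM177 by the rule. The lowest in both were CDH7 (-1.12 and -0.90), the thromboxane receptor gene TBXA2R (-0.77 and -1.06), CTSW (-0.76 and -0.99), IL32 (-0.73 and -0.99), NLE1, ZNF764, ZC3H3, AHNAK (-1.03 and -0.63), PRMT9 and SLC39A14. All 20 lay under 2-fold in at least 1 comparison except SPINT1. In 6AF minus DMSO, 0 of the 10 highest and 2 of the 10 lowest had an array at or above the 75th percentile of signals. On all 4 arrays, 6 of the 10 highest and 6 of the 10 lowest were above the floor.

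In 6AF minus DMSO 4 lists stood apart, all as lower and all with small medians. These were mature neutrophil and phagocyte genes (-0.28, 20 of 28 members lower by any amount), chemokines and inflammatory mediators (-0.23, 18 of 28), primary granule genes (-0.16, 14 of 18) and endoplasmic reticulum chaperones (-0.15, 16 of 24). In the first 2 lists, only 15 of 28 and 10 of 28 members had a DMSO or 6AF signal at or above the floor. Genes under the floor on all 4 arrays had an SD of 0.412 in this comparison. ITGAX (-1.10) and CXCL8 (-1.10) were the only members of the first 2 lists past 2-fold, and in the other 2 lists 0 members were. The fucosylation list had a median of -0.03 with 0 of 18 members past 2-fold; GMDS differed by 0.61, GFUS by -0.04, FUT4 by -0.05, FUT7 by 0.01 and FUT8 by -0.28. CEBPE, ITGAM and MYC differed by -0.04, 0.09 and -0.04. The primary granule list no longer stood apart with unmatched random lists or with lists matched on gene length, and neither it nor the chaperone list did with lists matched on the mean ATRA difference.

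When 6AF was combined with ATRA, interferon-stimulated genes stood higher than with ATRA alone. The list median of ATRA+6AF minus ATRA was 1.05 (2.07-fold), with 33 of 34 members higher by any amount and 18 of 34 by at least 2-fold. The middle 95% of random lists lay between -0.11 and 0.18. IFIT2, an interferon-induced antiviral gene, had log2 signals of 5.48, 9.78, 5.67 and 12.09 with DMSO, ATRA, 6AF and ATRA+6AF, so that the last exceeded ATRA by 2.31. RSAD2, which encodes viperin, was higher by 2.14, the oligoadenylate synthetase gene OAS2 by 1.87, CMPK2 by 1.84, IFIT5 by 1.77, HERC5 by 1.62 and IFIT1 by 1.56. IRF9, a subunit of the interferon-activated factor ISGF3, was higher by 1.07 and ISG15 by 1.06, and IRF7 (-0.12), under the floor on both arrays, was the single lower member. In 6AF minus DMSO the same list had a median of 0.04, within the range of random lists, with IFI6 past 2-fold. Only 16 of the 34 members had a DMSO or 6AF signal at or above the floor, so this median could miss differences in dim members. All 34 members were higher in ATRA+6AF than in DMSO, by a median of 4.45. Median differences from ATRA were 1.07 for the 23 members past 2-fold in ATRA minus DMSO and 0.51 for the other 11. The ATRA array enters both the split and these differences, so its noise biases the comparison of the 2 parts. Some of the other 11 were dim, since 28 of 34 members had a DMSO or ATRA signal at or above the floor.

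**Figure D3:**
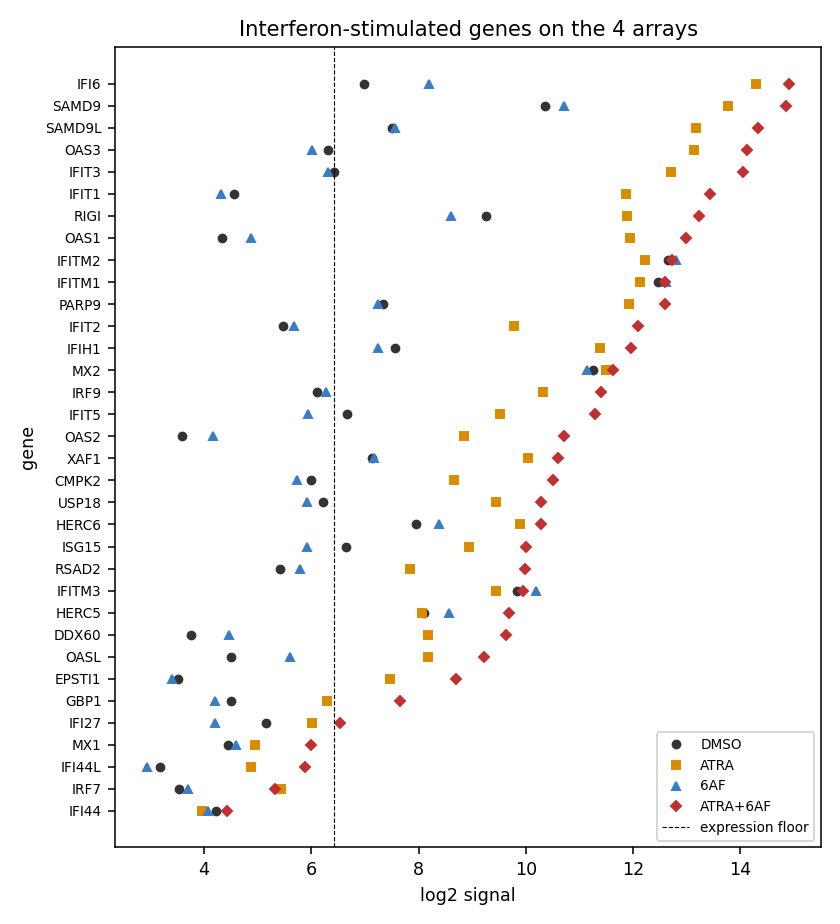
Log2 signals (x axis) of the 34 measured interferon-stimulated genes (y axis, sorted by the ATRA+6AF signal) on the DMSO, ATRA, 6AF and ATRA+6AF arrays; the dashed line is the expression floor of 6.42. The ATRA+6AF signal lies above the ATRA signal in 33 of 34 genes, while DMSO and 6AF lie close together in most genes. Only 16 of the 34 genes reach the floor on the DMSO or 6AF array.

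Outside that list, the 10 genes highest in ATRA+6AF minus ATRA also included ARAP2 (2.15), the matricellular gene THBS1 (2.1), SPP1, which encodes osteopontin (1.76), CEACAM5 (1.75) and JAML (1.75), a junctional adhesion molecule of leukocytes. Of these 10 genes, 7 had an array at or above the 75th percentile of signals, but only 1 was above the floor on all 4 arrays. ARAP2 passed the floor only on the ATRA+6AF array (6.72). Of the 142 higher genes, 69 (48.6%) belonged to the 823 genes whose mean ATRA difference over both backgrounds was at least 1, a set that made up 9% of genes above the floor. The 10 lowest genes were TAS2R20 (-2.17), CYP26A1 (-1.52), IL17D (-1.35), HCP5 (-1.34), PITX1 (-1.31), UNC93A, CASR, KRTAP22-1, CLYBL and DUSP15. Apart from PITX1, with signals from 7.54 to 9.56, these lay under the floor on at least 1 array. Only 2 of the 38 lower genes, against 50 of the 142 higher genes, had an array at or above the 75th percentile of signals. Quantile normalization gave 121 higher and 59 lower genes.

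Over the 823 ATRA-higher genes, the median of ATRA+6AF minus ATRA was 0.27, and 78% of them were higher with the combination than with ATRA. Over the 1090 ATRA-lower genes it was -0.06, and 55% were lower. The median ATRA difference of the higher set was 1.67 without 6AF and 2.01 with it, and that of the lower set was -1.41 and -1.39. The major axis of the 2 ATRA differences over all genes above the floor had a slope of 1.08. Across 9169 genes, ATRA+6AF minus ATRA had a weak Spearman correlation with gene length (0.15). Whether a difference between arrays that follows gene length added to the median of 0.27 was not tested.

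Apart from interferon genes, 5 lists stood apart as higher and 3 as lower in ATRA+6AF minus ATRA. Mature neutrophil and phagocyte genes had a median of 0.30, with 22 of 28 members higher by any amount. CEACAM8 (1.18) and CLEC7A (1.03) passed 2-fold, ITGAM differed by 0.38, and ITGB2 by 0.69. The glycolysis and hypoxia list (0.23, 21 of 25 higher) included NDRG1 (1.10), HK2 (0.88) and KDM3A (0.86). Lysosome and autophagy genes had a median of 0.19 with ULK1 (1.11) past 2-fold, secondary and tertiary granule genes 0.18 with MMP8 (1.67), S100A12 (1.66), S100A8 (1.36) and S100A9 (1.16) past it, and chemokines 0.14 with IL1A (1.15). The lower lists were cell cycle genes (-0.13, 35 of 49 lower by any amount), ribosome biogenesis genes (-0.13, 18 of 25) and primary granule genes (-0.16, 13 of 18), none with a member past 2-fold. Of these 8 lists, only the glycolysis and primary granule lists still stood apart among random lists matched on the mean ATRA difference, and the other 6 medians lay within the range of those lists. Under quantile normalization and under cyclic loess the late granule, primary granule and ribosome biogenesis lists no longer stood apart, nor did they or the chemokine list with unmatched random lists. The primary granule, ribosome biogenesis and cell cycle lists did not stand apart among random lists matched on gene length. The retinoic acid list (0.15), myeloid transcription factors (0.16), progenitor genes (-0.07), monocyte and macrophage markers (0.15), the fucosylation list (0.03) and the selectin ligand list (0.05) lay within the range of random lists. CEBPE, MYC, FUT4 and FUT8 differed by -0.05, -0.14, 0.03 and 0.03, GMDS, GFUS and FUT7 by 0.11, -0.30 and -0.09.

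Compared with DMSO, the combination had 933 genes higher and 1287 lower, or 1115 and 968 under cyclic loess. The 5 highest genes were TGM2 (11.69), CLC (10.51), CCL24 (10.46), CCL2 (10.15) and S100A8 (9.61), and the 5 lowest were CYTL1 (-9.84), BCL2 (-6.63), CST7 (-6.23), EBF3 (-6.15) and BCL11A (-5.80). By list, 9 stood apart as higher and 3 as lower. Glycolysis and hypoxia genes (0.22) stood apart here, and myeloid transcription factors (0.20) and ATF4-linked genes (-0.34) did not, although the ATF4-linked list stood apart as lower with unmatched or length-matched lists. Neither of the last 2 lists stood apart in ATRA+6AF minus ATRA. The glycolysis list did not stand apart under quantile normalization, with unmatched random lists or with lists matched on gene length.

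In the presence of 6AF, the ATRA difference (ATRA+6AF minus 6AF) set 11 lists apart as higher and 2 as lower. Interferon-stimulated genes had a median of 4.28, mature neutrophil and phagocyte genes 2.19, chemokines 1.62 and lysosome genes 1.05, and the lower lists were ribosome biogenesis (-1.02) and cell cycle genes (-0.55). The retinoic acid list had a median of 0.98 with 8 of 20 members 2-fold higher, against 1.94 and 10 without 6AF. Among random lists matched on the mean ATRA difference it lay below the range with 6AF and above it without 6AF. That mean holds both differences, so a list above its matches in either difference tends to lie below them in the other. The placements are therefore a single finding, not separate support for a weaker response. CYP26A1 differed by 0.35 with 6AF present against 1.85, and PLAAT4 by 0.92 against 2.02, whereas TGM2, ASB2 (5.77) and TNFAIP2 (5.68) kept differences as large as without 6AF. CYP26A1 was dim, with log2 signals of 4.83, 6.68, 4.81 and 5.16 with DMSO, ATRA, 6AF and ATRA+6AF. Only the ATRA signal passed the floor of 6.42, so its smaller difference with 6AF is uncertain. Gene by gene, 12 of the 20 members had a larger ATRA difference with 6AF, with a median difference of differences of 0.14, inside the range of random lists. Selectin ligand genes stood apart as higher (0.33, 6 of 28 higher and 3 lower), under every scaling and matching, with B3GNT5 (1.69), CD24 (1.63) and CD44 (1.14) past 2-fold. Their difference of differences (0.22) did not stand apart among signal-matched lists. The progenitor and ATF4-linked lists did not stand apart here, and the glycolysis list (0.22) did so only with signal-matched lists.

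Among genes above the floor, departures from additivity on the log2 scale were mostly positive. The difference of differences, which carries the noise of all 4 arrays, was at least 1 in 423 genes and at most -1 in 153 of 9612. The split was 336 and 199 under quantile normalization, and with no floor it was close to even, 710 and 660. The 5 highest genes were THBS1 (3.37), IFIT5 (2.5), the interferon-inducible gene SLFN5 (2.43), SLC24A4 (2.33) and SPP1 (2.33). Of these, 4 had an array at or above the 75th percentile of signals, but only SPP1 was above the floor on all 4 arrays. THBS1, IFIT5, SLFN5 and SLC24A4 lay under the floor on the 6AF array (5.78, 5.94, 5.24 and 4.37). The 5 lowest were TAS2R20 (-3.63), HCP5 (-2.15), KRTAP22-1 (-1.89), HSF2BP (-1.85) and EFCAB13 (-1.68), none with an array at or above the 75th percentile of signals. By list the interferon genes had the largest median (0.99, 16 of 34 members past 2-fold), followed by mature neutrophil and phagocyte genes (0.54) and lysosome and autophagy genes (0.39). The last 2 lists no longer stood apart among random lists matched on the mean ATRA difference, whereas the interferon list did.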

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

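The tests that matched random lists on the ATRA difference or on gene length, those of gene length and dim probes in the difference of differences, and the question of a difference between cultures were chosen after the result was seen. Mature neutrophil and phagocyte genes had a median of -0.28 in 6AF minus DMSO and 0.30 in ATRA+6AF minus ATRA, a median difference of differences of 0.54. Chemokines and inflammatory mediators had medians of -0.23 and 0.14, with a median difference of differences of 0.21. Only 15 of 28 phagocyte and 10 of 28 chemokine members had a DMSO or 6AF signal at or above the floor. Neither list's difference of differences stood apart among random lists matched on the mean ATRA difference, and that of the chemokine list did not with unmatched random lists. THBS1 was lower with 6AF alone (-1.27) and higher with 6AF in ATRA-treated cells (2.1), a difference of differences of 3.37. PHLDA1 differed by -1.08 and 1.17 (2.25) and NDRG1 by -1.01 and 1.10 (2.11), where independent lists would share 0.24 such genes. HCP5 was higher with ATRA alone (1.04) and lower with ATRA in the presence of 6AF (-1.11), a difference of differences of -2.15. None of these contrasts between backgrounds could be tested, since each rests on 1 array per treatment. Among the 3739 unnamed transcript clusters, which no comparison of genes used, 88 were at least 2-fold higher in both ATRA comparisons. That is 5.76% of the 1528 above the floor, against 7.13% of named genes.

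Interferon-stimulated genes were higher in ATRA+6AF than in ATRA by a median of 1.05. The tables argue against a proportionally larger ATRA response of all genes as the whole cause, because the list's median exceeded the medians of all random lists matched on the mean ATRA difference (percentile 100), whose middle 95% ended at 0.46. They argue against scaling, since the lowest median over the 3 other scalings was 1.02, and against a trend with gene length, since the list lay at percentile 100 of length-matched lists and its genes were short (median span 20.8 kb, against 25.9 kb for all genes). A difference between these cultures or arrays that is not due to 6AF stays open and cannot be told apart from an effect of 6AF with 1 array per treatment. The hypothesis that 6AF raises the interferon programme of ATRA-treated NB4 cells may be worth testing in replicate cultures.

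The difference of differences was at least 1 in 423 genes and at most -1 in 153. The 423 higher genes were long, with a median span of 38.3 kb against 27.7 kb for random genes of the same signal (percentile 100), which is what a difference between arrays that follows gene length predicts; across genes the Spearman correlation with length was weak (0.174). Dim probes alone are unlikely to account for them, because 61% of the 423 genes had all 4 arrays at or above the floor. That share was below the 84.4% of all genes considered, so dim genes were over-represented and may have added to the count. For the 153 lower genes length was not set apart (percentile 19.57), and 46.4% had all 4 arrays above the floor, which lies between the values that would settle the matter. RNA quality of single cultures was not measured here, and a different action of 6AF with and without ATRA stays open for both groups.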

How the results depend on the processing

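The matching of random lists on the ATRA difference or gene length and the choice of interferon members above the floor were chosen after the result was seen. No paired analysis was possible because the labels carry no replicate numbers and no result comes from a test. With 1 array per treatment, no replicate could be left out. A model of additive ATRA and 6AF effects was not fitted, since its 1 residual degree of freedom is the difference of differences. Signal over background limits the dim genes. Genes under the floor on all 4 arrays had an SD of 0.424 in ATRA+6AF minus ATRA. Counts moved with the threshold and the floor, as a count must when fewer or more genes can pass. At 1.5-fold they were 4051 (ATRA minus DMSO), 520 (6AF minus DMSO), 4257 (ATRA+6AF minus DMSO), 1065 (ATRA+6AF minus ATRA), 4130 (ATRA+6AF minus 6AF), 2112 (difference of differences), 2803 (both ATRA comparisons) and 23 (both 6AF comparisons), and at 3-fold, in the same order, 841, 2, 960, 19, 949, 71, 646 and 0. The main counts were 2011, 54, 2220, 180, 2148, 576, 1386 and 1. A floor at the 75th percentile gave 1047, 8, 1276, 52, 1278, 188, 817 and 0. Without a floor, 6AF minus DMSO had 233 genes, ATRA+6AF minus ATRA 404, the difference of differences 1370 and both 6AF comparisons 7, and the other counts stayed within 1.5 times. Other scalings kept every count within 1.5 times except that quantile normalization left 0 genes in both 6AF comparisons. The median difference of differences of ATRA-lower genes, 0.03, turned to -0.04 with the higher floor and -0.069 under quantile normalization. The cause was not tested. The 2 correlations of disjoint differences moved by less than 0.1 under every alternative run. No list median moved by over 1.5 times under another scaling, and no list that stood apart changed sign in any alternative. Restricting lists to members above the 75th percentile, which drops dim members, gave larger medians in ATRA minus DMSO, ATRA+6AF minus DMSO and ATRA+6AF minus 6AF: 4.97, 4.85 and 5.03 for the retinoic acid list, 2.58, 2.85 and 3.57 for mature phagocyte genes, 1.77, 1.37 and 1.61 for late granule genes, 2.35, 2.58 and 2.91 for monocyte and macrophage markers, 4.58, 4.82 and 5.21 for chemokines, -1.72, -2.60 and -2.88 for progenitor genes, and -0.78, -0.90 and -0.70 for p53 targets. A member was kept when the higher of the compared arrays passed. Dim members that did not differ were thus dropped, so larger medians are partly built in. Few members remained: in ATRA minus DMSO 6 retinoic acid, 5 late granule, 3 monocyte and macrophage, 5 progenitor and 4 p53 genes. The higher floor also gave 4.03 for interferon genes with ATRA, 1.21 and 1.51 for myeloid transcription factors with the combination over DMSO and over 6AF, 0.85 for NOTCH genes over 6AF (4 members), and, reversed in sign from medians of 0.19 and 0.15, -0.90 and -0.56 for eosinophil markers (5 members) with ATRA and with the combination over DMSO. Means in place of medians, in the same 3 comparisons, were 1.02, 1.32 and 1.27 for late granule genes, 1.28, 1.11 and 1.34 for primary granule genes, whose medians were negative and stood apart with length-matched lists but not with signal-matched ones, and 2.56, 2.71 and 2.87 for chemokines, and 2.52 and 2.502 for the retinoic acid list in the last 2. Matched on the mean ATRA difference, random lists left 3 of the 9 lists of ATRA+6AF minus ATRA standing apart (interferon, glycolysis and hypoxia, and primary granule genes) and 2 of the 7 of the difference of differences (interferon, and glycolysis and hypoxia, the latter lost with unmatched or length-matched lists). Unmatched lists left 5 of 9 and 5 of 7. Other matchings also added lists, all as lower unless stated: primary granule genes over DMSO and over 6AF with the combination (unmatched), erythroid and megakaryocyte markers in ATRA+6AF minus ATRA (all 3 other matchings), eosinophil markers in 6AF minus DMSO (length) and selectin ligand genes in the difference of differences (unmatched, higher). In ATRA+6AF minus 6AF, lists matched on the mean ATRA difference left 2 of 13 (interferon and selectin ligand genes) and turned the retinoic acid list from higher to lower. Cyclic loess added progenitor genes there. In ATRA minus DMSO that matching left 1 of 13 (retinoic acid genes) and turned the interferon list from higher to lower (percentile 0.55). In ATRA+6AF minus DMSO it left 2 of 12 (interferon and progenitor genes). The mean holds both ATRA differences, so placements in ATRA minus DMSO and ATRA+6AF minus 6AF are tied to each other. The interferon median of ATRA+6AF minus ATRA was 1.07 over the 28 members at or above the floor on the ATRA array. The 757 values of named genes moved by less than 1.5 times under the alternatives run.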

Other observations

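Gene families formed by the letters of the symbol, chosen after the data had been seen, gave groups that the fixed lists did not hold. The 153 families of at least 8 genes gave 918 values in 6 comparisons. Of these, 26 lay in the outermost 0.1% on either side of 2000 random lists. Families of unrelated genes would give 1.8. Genes of a family can vary together between cultures, and the comparisons share arrays. How many such values chance gives for these families was therefore not measured, and 1.8 is no baseline for the 26. With ATRA, RNA polymerase subunit genes (POLR, 30 genes) had a median of -0.65 with 8 lower by 2-fold and 0 higher, translation initiation factor genes (EIF, 47) a median of -0.44, and DDX genes, which encode RNA helicases (30), a median of -0.57. Genes with CD symbols, most of them leukocyte surface molecules (47), had a median of 0.90, with 22 higher and 5 lower. Among random lists matched on gene length, POLR and CD still met the 0.1% rule, while EIF (percentile 1.15) and DDX (0.57) did not.

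Mitochondrial ribosomal protein genes were lower in ATRA+6AF than in ATRA. Large subunit genes (MRPL, 47 genes) had a median of -0.16 and small subunit genes (MRPS, 27) of -0.27, with 11 and 6 members higher by any amount and only 1 and 0 lower by 2-fold. These genes are short (median spans of 8.1 and 11.1 kb), and among random lists matched on gene length the medians lay at percentiles 0.4 and 0, so that only MRPS still met the 0.1% rule by which families were picked. In 6AF minus DMSO their medians were -0.04, which turned to 0.01 under quantile normalization, and 0.04, and in ATRA minus DMSO -0.57 and -0.48. Cytosolic ribosomal protein genes (RPL, 33) had medians of 0.07 with 6AF alone and -0.04 in ATRA+6AF minus ATRA, both inside the range of length-matched lists. The symbol families ZSCAN (10 genes) and KDM (12) also met the 0.1% rule with 6AF alone. Their medians were -0.46 and -0.29, with 0 members higher by any amount. In ATRA+6AF minus ATRA the ZSCAN median was 0.295. Neither of these families was placed among length-matched lists or under other scalings. Keratin-associated protein genes (KRTAP, 12), which are not blood cell genes, had a median of -0.43 in ATRA+6AF minus ATRA and 0.70 in ATRA minus DMSO, and the 8075 genes under the floor on all 4 arrays had medians of -0.06 and 0.17 in the same comparisons. Apart from ZSCAN, KDM and the MRPL median in 6AF minus DMSO, every family median printed here kept its sign under the 3 other scalings.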
